A study of Mus musculus with 2 samples.

How the data were processed

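The samples were T cells from the colons of Rag-deficient mice, which had received CD4 T cells from donors. Such mice make no mature T or B cells of their own. Recipients of wild-type cells are called WT-labelled here, and recipients of BCL-6-deficient cells KO-labelled. Cells positive for the T cell receptor beta chain and CD4 were sorted, tagged with 1 hashtag antibody per mouse and pooled into 1 gene expression library of 5′ chemistry, per the labels' protocols. The hashtag library of the series was used only through the authors' assignment of cells to mice.

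Per the submitters' processing notes, Cell Ranger 3.1.0 and Seurat 3.1.5 were used, with the genome builds GRCm38 and mm10 named. The authors deposited raw UMI counts for 11971 genes in 18860 cells, with a per-cell annotation giving the mouse, genotype, cluster, cell subset and clonotype. In that annotation the authors also deposited a percent of mitochondrial UMIs and a doublet score for each cell. The cell filter is not given in the sources used here. Every gene in the table had a UMI in at least 19 cells and every cell had at least 501 genes. The UMI sum of every cell equalled the deposited count of that cell. No doublet caller was run here, and the highest deposited doublet score was 0.354.

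The mouse was the replicate, with 6 KO-labelled and 6 WT-labelled mice. The deposited genotype of each cell matched the hashtag table in all 18860 cells. All 12 mice shared 1 pooled library, so no library batch separates the genotypes. Donors of the T cells did not enter the tests, so whether donor differences add to those between genotypes is open. Mice contributed 1409 to 1736 cells and 4252124 to 5523025 UMIs each. The authors' cluster labels were used: recirculating, cytotoxic, Th17, cycling, regulatory, and clusters 1 and 3, which carry only a general CD4 label and are called unnamed 1 and unnamed 3.

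UMIs were summed per mouse, and per mouse and cluster, and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, filterByExpr, no covariates, two-sided). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Within clusters, mice with fewer than 20 cells were left out, which left 5 KO-labelled and 3 WT-labelled mice for regulatory cells. The standard error of a log2 fold change was its size divided by the square root of F. CPM values were computed from the summed counts. Effects in recirculating and cytotoxic cells were compared with limma 3.58.1 on the difference between the clusters within each mouse.

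Cluster shares, depth, clonotype measures and shares of cells with a UMI were compared with exact permutation tests over the 924 assignments of 12 mice, two-sided, for which the smallest p is 0.00216. For shares of cells with a UMI, each cell was thinned to 1500 UMIs, which left out 491 cells of KO-labelled and 407 of WT-labelled mice. The 16 gene lists were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The lists were stem-like and naive-memory, Tfh, Th1, Th17, Th2, Treg, cytotoxic, inhibitory receptors, BCL6-repressed genes, tissue residence, cell cycle, interferon-stimulated, early activation, heat shock and dissociation stress, glycolysis and pathogenic cytokines. Of their 197 genes, 188 were in the table, as were 33 of 51 markers of T cells and other cell types.

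Tests, lists, markers, the alternatives listed first below and the rule for named genes were fixed before the data were examined. The rule took Bcl6, a panel of 19 genes, and the 8 largest rises and 8 largest falls over all cells. In each cluster it took the 3 largest of each direction. Rises and falls needed an adjusted p under 0.05, a mean log2 CPM of at least 4 and no overlap in CPM between genotypes. Receptor segments, immunoglobulin genes and gene models without a standard name were passed over. Genes named because they changed in many clusters, Cd4 within clusters, and the ribosomal protein genes were chosen after their values were seen. Lists within clusters were not among the tests fixed beforehand, and only the Th17, cytotoxic, stem-like and naive-memory, and Treg lists are given there. For a list, up to 4 members with the smallest p were named.

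Alternatives chosen beforehand were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 test, equal numbers of cells per mouse, every cluster given the same weight, 500 UMIs or no thinning for shares of cells with a UMI, log odds of cluster shares, no cycling cells, no receptor segments, a stricter cell filter and each mouse left out in turn. The stricter filter removed 0 cells and so tested nothing. Giving every cluster the same weight, or weighting clusters alike, means throughout that a cluster had the same weight in each mouse. That weight was its share of all cells pooled, so large clusters counted for more than small ones.

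Added after seeing the data were a fit without KO-labelled mice 1 and 2, lists with clusters weighted alike, and a pair of relabellings of the cells. Both relabellings used cells of other WT-labelled mice as the reference and left out the 919 genes called within any cluster. The first gave each cell the most frequent label among its 30 nearest reference cells, over 30 components of 2000 genes. It returned the deposited label for 66.8% of WT-labelled cells, but for only 14.0% of unnamed 1 and 3.03% of unnamed 3 cells among them. The second, a class-balanced logistic classifier over 50 components of 3000 genes (scikit-learn 1.9.0), was chosen because of that low recovery, after the genotype shares from the first had been seen. It returned the deposited label for 68.5% of WT-labelled cells, and for 62.9% of unnamed 1 and 51.7% of unnamed 3 cells. The results of both are given. Clonotype measures and the 10 Mb window around Bcl6 were also set after the data had been opened.

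The gene-wise test was checked on simulated counts with 200 changed genes. Over the 9861 genes of the all-cell comparison it recovered 74% of 1.5-fold and 94% of 2-fold changes, and 4% of its calls were false. Over the 1754 genes tested in regulatory cells it recovered 24% and 54%, and 6.02% of its calls were false. The false share was 7.58% in Th17 cells and 2.80% to 4.69% in the other clusters. Simulated counts were drawn for each gene on its own, so the false shares need not hold for the real calls. Gene positions are from GENCODE M21 on GRCm38, matched by symbol. Other versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.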

Results

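Colonic CD4 T cells were profiled from 12 Rag-deficient mice, 6 given wild-type and 6 given BCL-6-deficient CD4 T cells, a transfer that causes colitis. The design asks how the loss of BCL-6, a transcriptional repressor needed for follicular helper T cells, alters T cells in the inflamed colon. The table held 57634998 UMIs in 18860 cells, 9708 from KO-labelled and 9152 from WT-labelled mice, with a median of 2772 UMIs and 1234 genes per cell. Cells of KO-labelled mice were shallower, with a median of 2630 ± 244 UMIs against 2945 ± 88.3 (SD, n = 6 mice each, exact permutation p = 0.0260, adjusted p = 0.0390 over 3 measures). The median mitochondrial share was 0.815% ± 0.00837 against 0.896% ± 0.0294 (exact p = 0.00216, adjusted p = 0.00649). The median number of genes per cell was 1212 ± 76.7 against 1275 ± 32.3 and did not pass (exact p = 0.0952).

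Bcl6 UMIs were higher, not lower, in KO-labelled mice. Bcl6 (chromosome 16, 23965052 to 23988852, minus strand, GRCm38) stood at 68.3, 65.5, 90.7, 79.9, 86.7 and 89.9 CPM in KO-labelled mice 1 to 6 and at 55.7, 49.3, 61.4, 57.2, 49.7 and 70.5 CPM in WT-labelled mice 1 to 6. The log2 fold change was 0.48 ± 0.10 (SE, adjusted p = 0.00398), and it was 0.59 ± 0.09 with each cluster given the same weight in every mouse. The chemistry reads the 5′ end of transcripts and the labels do not say which part of the gene was removed, so the count cannot check the labels. Directions below therefore refer to the deposited labels.

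Cytotoxic cells made up a smaller part, and cells of the cluster unnamed 1 a larger part, of the T cells of KO-labelled mice. The cytotoxic share was 8.63% ± 4.52 against 33.2% ± 6.77 (SD, n = 6 each, exact permutation p = 0.00216, adjusted p = 0.00758). The unnamed 1 share was 32.6% ± 8.71 against 8.37% ± 2.25 with the same p. With the deposited labels, Th17 cells, which make interleukin 17, were also fewer at 5.83% ± 2.78 against 18.01% ± 5.98 (exact p = 0.00433, adjusted p = 0.00758). The cluster unnamed 3 was larger at 23.1% ± 11.5 against 7.55% ± 1.60 (exact p = 0.00433, adjusted p = 0.00758). Recirculating cells took 20.8% ± 12.2 against 25.2% ± 3.33 (exact p = 0.403), cycling cells 6.41% ± 1.80 against 6.28% ± 1.84 (exact p = 0.885) and regulatory cells 2.58% ± 1.45 against 1.36% ± 0.734 (exact p = 0.0866, adjusted p = 0.121). KO-labelled mice varied widely, from 6.83% to 40.0% for recirculating cells.

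Genes that define the clusters differed between genotypes, so the shares were recomputed with labels assigned without the 919 genes called within any cluster. By nearest cells of WT-labelled mice, cytotoxic cells took 15.4% against 29.98% (exact p = 0.00216, adjusted p = 0.00758) and unnamed 1 took 5.204% against 2.29% (exact p = 0.00649, adjusted p = 0.0152). By the classifier chosen after that result was seen, they took 14.8% against 28.1% (exact p = 0.00649, adjusted p = 0.0379) and 24.1% against 13.7% (exact p = 0.0108, adjusted p = 0.0379). The Th17 difference did not pass with either (adjusted exact p = 0.0606 and 0.0657), nor did that of unnamed 3 (adjusted exact p = 0.816 and 0.0833). Recirculating cells were at 60.6% against 43.7% by nearest cells (exact p = 0.00216, adjusted p = 0.00758) and at 21.3% against 21.1% by the classifier (exact p = 0.959), so no direction can be given for them. The deposited label was returned for 37.8% of cells of KO-labelled and 66.8% of those of WT-labelled mice by nearest cells, and for 61.3% and 68.5% by the classifier.

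**Figure D1:**
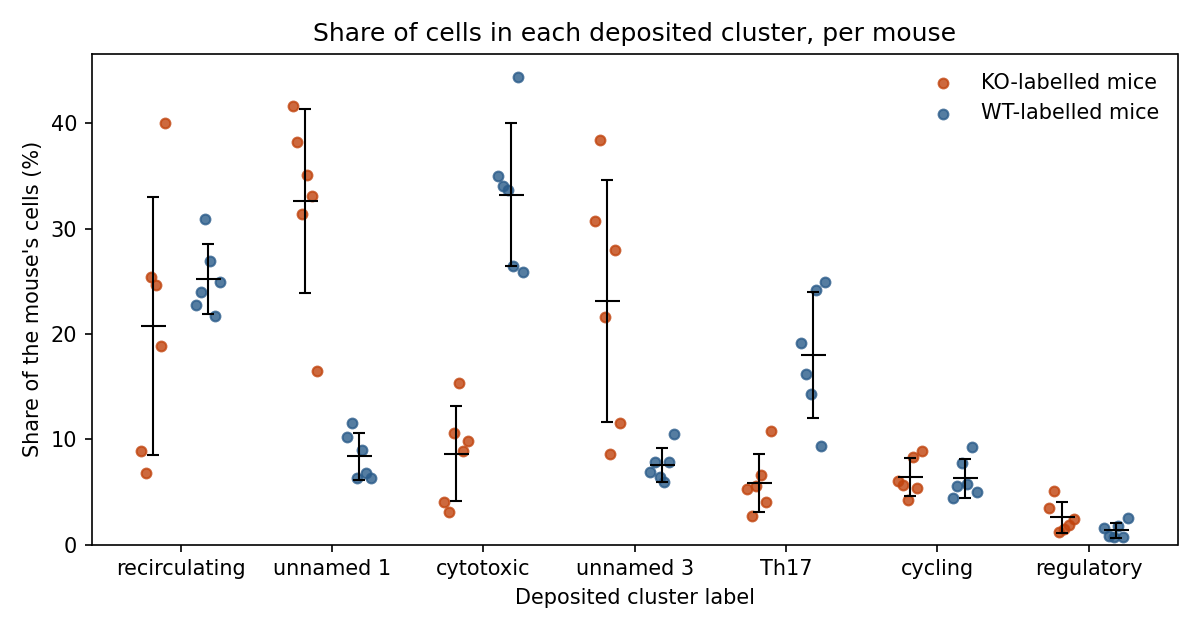
Share of each mouse's cells (percent, vertical axis) in each deposited cluster (horizontal axis), with 1 point per mouse and the mean and SD of 6 mice in black. The cytotoxic points of KO-labelled mice lie below all those of WT-labelled mice and their unnamed 1 points lie above, while recirculating shares of KO-labelled mice spread from 6.83% to 40.0%.

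Over all CD4 cells, Cxcl3, Cd8a, Eomes and Gzmk were among the genes with the largest falls in KO-labelled mice, and Itsn1, Rasgrp4 and Lmna had the largest rises, in each case among called genes with a mean log2 CPM of at least 4 and no overlap between genotypes. The chemokine Cxcl3 fell by 3.96 ± 0.37 on the log2 scale, from 162 ± 53.6 to 10.0 ± 8.09 CPM (SD, n = 6 each, adjusted p = 5.9e-06). Eomes, a transcription factor of cytotoxic cells, fell by 3.21 ± 0.33 (adjusted p = 1.3e-05) and the granzyme gene Gzmk fell by 2.23 ± 0.16 (adjusted p = 6.0e-07). Cd8a fell by 3.44 ± 0.42, from 39.7 ± 17.7 to 3.64 ± 2.16 CPM (adjusted p = 5.6e-05). The other large falls were in Tff1, a trefoil peptide gene (log2 fold change -3.11), Pde5a (-2.40), Esm1 (-2.24) and the T cell surface receptor gene Cd7 (-2.24). CPM values of Tff1 in KO-labelled mice were 11.995 or lower but for mouse 6, at 36.6. Gzmk (chromosome 13, 113171608 to 113225908) and Esm1 (113209659 to 113218098) overlap on opposite strands, and whether the counting used strand is not given in the sources used here, so their falls cannot be fully told apart.

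By the same rule the largest rises were in Itsn1, an endocytic scaffold gene on chromosome 16 (91729281 to 91920597), at 28.5 ± 10.3 against 3.28 ± 0.750 CPM (log2 fold change 3.099 ± 0.25, adjusted p = 2.3e-06), and Rasgrp4, an activator of Ras (2.90 ± 0.39, adjusted p = 1.2e-04). Lmna, which encodes lamin A, rose by 2.70 ± 0.47 (adjusted p = 0.00107), with 55.0 to 486 CPM across KO-labelled and 23.1 to 52.5 CPM across WT-labelled mice. Atf3, Vav3, Crip2, Tiparp and Spryd7 rose by 1.53 to 2.09. In all, 1405 of 9861 genes were called, 694 up and 711 down. With every cluster given the same weight 952 were called, among them 804 of the 1405, all in the same direction. Falls were then smaller, at -2.21 for Cd8a, -1.83 for Eomes, -1.40 for Pde5a and -1.40 for Gzmk. Without KO-labelled mice 1 and 2, which had the fewest recirculating and cytotoxic cells, 770 were called, 723 of them shared and in the same direction.

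**Figure D2:**
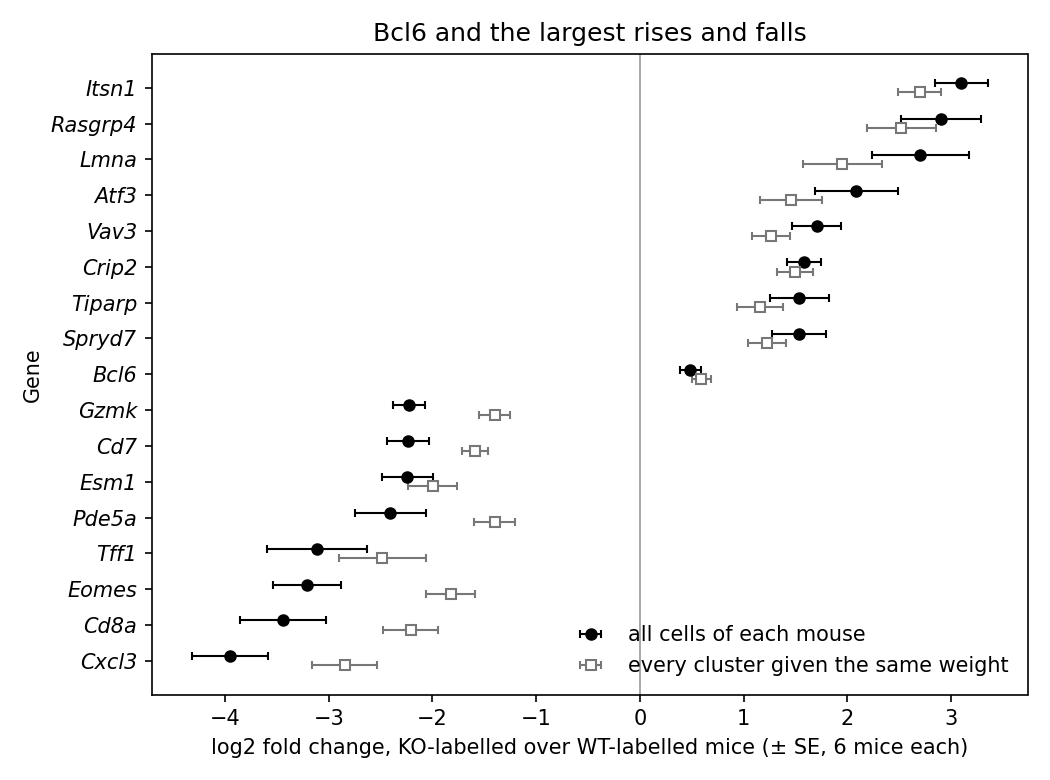
The log2 fold change of KO-labelled over WT-labelled mice (horizontal axis) for Bcl6 and the 8 largest rises and 8 largest falls (vertical axis), with SE bars. Filled circles are for all cells. Open squares are with each cluster given the same weight in every mouse, its share of all cells pooled. All 8 falls and 8 rises keep their direction and are smaller with clusters weighted alike, in proportion most so for Eomes, Pde5a, Gzmk and Cd8a.

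Among the panel of stem-like, helper and effector genes, Tcf7, which encodes the stem-like T cell factor TCF-1, stood at 115 ± 9.06 against 111 ± 10.97 CPM (log2 fold change 0.05 ± 0.07, adjusted p = 0.696). Lef1, its relative, fell by 0.63 ± 0.16 (adjusted p = 0.0122), Slamf6 fell by 0.54 ± 0.17 (adjusted p = 0.0389) and the inhibitory receptor gene Pdcd1 fell by 0.52 ± 0.17 (adjusted p = 0.0462). The chemokine Ccl5 fell by 1.67 ± 0.17, from 5293 ± 1300 to 1667 ± 434 CPM (adjusted p = 1.5e-05), and by 0.86 ± 0.09 with every cluster given the same weight. Id2 rose by 0.20 ± 0.06 (adjusted p = 0.0453). Ifng, Il17a, Il21, Foxp3, Gzmb, Tbx21, Prdm1, Icos, Il7r and Ccr7 did not pass, with adjusted p from 0.0872 for Il17a to 0.937 for Prdm1. Cxcr5 had too few UMIs for the gene-wise test. The calls of Slamf6, Pdcd1 and Id2 lay near the threshold. Slamf6 lost its call without any 1 of KO-labelled mice 1, 2 and 5 or WT-labelled mice 2, 3, 4 and 6 (adjusted p from 0.0542 to 0.0963). Pdcd1 lost it without any 1 of KO-labelled mice 1, 2, 3, 5 and 6 or WT-labelled mice 1, 2, 4, 5 and 6 (adjusted p from 0.0546 to 0.109), and Id2 without any 1 of KO-labelled mice 1, 2, 4 and 5 or WT-labelled mice 1, 2, 3 and 6 (adjusted p from 0.0588 to 0.105). Pdcd1 and Id2 also lost theirs with every cluster given the same weight (adjusted p = 0.131 and 0.106) and with cycling cells left out (0.0673 and 0.0559), and Slamf6 with equal numbers of cells (0.0693). All 3 lost theirs without KO-labelled mice 1 and 2 (adjusted p = 0.157 for Slamf6, 0.192 for Pdcd1 and 0.217 for Id2). The direction of Il17a was not stable, at -0.95 (adjusted p = 0.0872) over all cells, -1.16 (adjusted p = 0.00802) without WT-labelled mouse 5, -1.09 (adjusted p = 0.0403) without cycling cells and 0.32 (adjusted p = 0.4929) with every cluster given the same weight. Ifng was at 0.43 (adjusted p = 0.115), at 0.52 (adjusted p = 0.0393) without KO-labelled mouse 6 and at 0.08 (adjusted p = 0.816) with every cluster given the same weight.

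The follicular homing receptor gene Cxcr5 was found in fewer cells of KO-labelled mice. After thinning to 1500 UMIs, 0.0339% ± 0.0373 of cells against 0.319% ± 0.169 had a Cxcr5 UMI (SD, n = 6 each, exact permutation p = 0.00433, adjusted p = 0.0433 over 10 genes). Unthinned, the shares were 0.0428% and 0.514% (adjusted exact p = 0.0649), and at 500 UMIs the difference did not pass either (adjusted exact p = 0.212). It was also lost without any 1 of KO-labelled mice 1, 2, 3, 5 and 6 (adjusted exact p from 0.0541 to 0.0649), so the call is a weak one. In WT-labelled mice these were 26 of 2789 cytotoxic cells but 1 of 2272 recirculating, 1 of 633 unnamed 3 and 0 of 1648 Th17 cells. In KO-labelled mice they were 1 of 733 cytotoxic and 2 of 2078 unnamed 3 cells, so the share within cytotoxic cells was 0.136% against 0.932%, which was not tested. The median UMIs per cell, averaged over WT-labelled mice, were 2468 in cytotoxic, 3280 in recirculating and 3465 in Th17 cells. Shares for Bcl6 (9.65% against 7.52%, adjusted exact p = 0.0794, and 0.0433 at 500 UMIs), Slamf6 (2.91% against 4.26%, adjusted exact p = 0.0794), Tcf7 (15.8% against 15.7%, adjusted exact p = 0.924), Il7r, Ifng, Il17a, Foxp3 and Gzmb did not pass.

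Of the 16 gene lists, 6 passed camera with the preset correlation and 0 with an estimated one. With the estimated correlation the adjusted p was 0.318 for the Th17, cytotoxic, interferon-stimulated and heat shock lists. It was 0.213 for inhibitory receptors and 0.627 for glycolysis. The directions were the same with either correlation, but whether a list passed depended on that setting. With fry the adjusted p was 0.0293 for Th17, 0.0225 for cytotoxic, 0.0287 for interferon-stimulated, 0.0182 for heat shock and 0.00281 for inhibitory receptors. For glycolysis it was 0.0817. With the preset correlation the Th17 list was lower, with 9 of 14 members down and 2 up (adjusted p = 2.4e-04), 11 and 2 adjusted over the list alone. Ccr6 fell by 2.69 ± 0.40 and Tmem176a by 1.20 ± 0.20, whereas Ahr, a sensor of aromatic ligands, rose by 0.79 ± 0.09. Within Th17 cells this list had 2 of 13 up and 1 down (median 0.03, adjusted p = 0.774), and of the 7 clusters it passed, lower, in recirculating (adjusted p = 3.4e-05, and 0.0498 with an estimated correlation) and unnamed 3 cells (adjusted p = 4.2e-07 and 0.0144). The cytotoxic list was lower, with 4 of 11 down and 1 up (adjusted p = 0.00572), 4 and 2 adjusted over the list alone, where Gzma (-1.56 ± 0.30) fell besides Gzmk and Eomes, and the receptor gene Klrk1 rose by 1.36 ± 0.23. This call was lost with every cluster given the same weight, where the median was 0.08 (adjusted p = 0.296), and without KO-labelled mouse 6 (adjusted p = 0.0870). Within clusters, at the preset correlation, the list was lower in cytotoxic cells (adjusted p = 0.00678) but higher in recirculating (0.0424), unnamed 3 (0.0485) and Th17 cells (0.00130). It passed in no cluster with an estimated correlation. Eomes is also a marker of natural killer cells, and their marker Klrb1c was lower too (-1.58, adjusted p = 0.0134). Inhibitory receptors were lower, with 4 of 9 down and 1 up (adjusted p = 7.8e-04), the same adjusted over the list alone, with falls in Tigit (-0.75 ± 0.09), Cd160 (-1.73 ± 0.22) and Lag3 (-1.51 ± 0.27) and a rise in the ectonucleotidase gene Entpd1 (0.67 ± 0.14). Interferon-stimulated genes were higher, with 7 of 15 up and 0 down (adjusted p = 2.4e-04), 10 and 0 adjusted over the list alone, among them Oasl2 (1.71 ± 0.30), Rtp4 (1.20 ± 0.28) and Bst2 (0.35 ± 0.08). Heat shock genes were lower, with 6 of 10 down and 1 up (adjusted p = 2.6e-04), 8 and 1 adjusted over the list alone, with Hspa8 at -0.29 ± 0.05, Hspa1b at -1.10 ± 0.19 and Dnajb1 at -0.59 ± 0.11, and with Atf3, named above, as the member up. Hspa1b and its near-identical copy Hspa1a (-1.13 ± 0.21) share reads, so their values are uncertain one by one. Glycolysis genes were lower, with 5 of 12 down and 2 up (adjusted p = 0.0497), 7 and 2 adjusted over the list alone, with Tpi1 at -0.56 ± 0.12 and Hk2 at 0.81 ± 0.19. The glycolysis call was lost without any 1 of KO-labelled mice 1, 2, 3 and 5 or WT-labelled mice 1, 4, 5 and 6 (adjusted p from 0.0560 to 0.147), with DESeq2 size factors (adjusted p = 0.0528), with fry (0.0817), with every cluster given the same weight (0.0654) and without KO-labelled mice 1 and 2 (0.115).

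The other 10 lists did not pass camera. Stem-like and naive-memory genes had 6 of 15 down and 1 up (adjusted p = 0.0949), the same adjusted over the list alone, with Satb1 at -0.52 ± 0.08, Klf2 at -0.58 ± 0.10 and Bach2 at 0.82 ± 0.19. That list passed with every cluster given the same weight (median -0.20, adjusted p = 7.1e-04), with fry (adjusted p = 0.0297) and without WT-labelled mouse 5 (adjusted p = 0.0400). Within clusters it was lower and passed camera with the preset correlation in recirculating, unnamed 1, cytotoxic, Th17 and regulatory cells, but not in unnamed 3 or cycling cells. With an estimated correlation it passed only in recirculating cells (adjusted p = 0.0132). The Tfh list had 4 of 12 down and 1 up (adjusted p = 0.165), 5 and 2 adjusted over the list alone, with Tox2 at -1.69 ± 0.27, Sh2d1a at -0.58 ± 0.10 and Maf at 0.58 ± 0.13, and passed with every cluster given the same weight (median -0.37, adjusted p = 0.00747). The BCL6-repressed genes had 3 of 14 up and 3 down (adjusted p = 0.842), 3 and 4 adjusted over the list alone, with a median log2 fold change of 0.04 and a mean of -0.02. Up and down counts were 1 and 3 of 16 for Th1 (5 and 4 adjusted over the list alone), 1 and 1 of 6 for Th2 (2 and 1), 2 and 1 of 11 for Treg (2 and 1) and 5 and 3 of 14 for tissue residence (5 and 4). They were 0 and 1 of 18 for cell cycle (0 and 1), 2 and 2 of 15 for early activation (4 and 3) and 2 and 2 of 11 for pathogenic cytokines (3 and 3), again with the counts adjusted over the list alone in brackets. The adjusted p was 0.397 for Th2 and Treg, 0.463 for Th1 and 0.842 for the other 4. The Treg list, with a median of 0.39 over all cells, was lower and passed with every cluster given the same weight (-0.17, adjusted p = 0.00747). Within clusters it was lower and passed camera with the preset correlation in 5 of 7, with adjusted p from 2.0e-09 in unnamed 3 to 0.0272 in recirculating cells. With an estimated correlation it passed only in unnamed 1 (adjusted p = 0.0277) and unnamed 3 (0.00516). It did not pass in regulatory cells (median 0.19, adjusted p = 0.134 with the preset correlation), so no direction can be given for this list. Median and mean also differed in sign for cell cycle (0.03 and -0.03) and early activation (0.04 and -0.05), and the Th1 list passed without KO-labelled mouse 4 (adjusted p = 0.0280). Among the cytokines, Il2 rose by 1.72 ± 0.32 and Csf2 rose by 0.99 ± 0.24.

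Markers of other cell types did not all match between genotypes. The immunoglobulin gene Igkc had 44 UMIs in KO-labelled and 536 in WT-labelled mice (log2 fold change -3.54, adjusted p = 7.0e-05), and the keratin gene Krt18 107 and 409 (-1.89, adjusted p = 1.3e-04). Klrb1c had 39 and 121 UMIs (-1.58, adjusted p = 0.0134) and the gamma-delta receptor gene Tcrg-C1 493 and 936 (-0.87, adjusted p = 0.0197). The myeloid marker Cst3 was also lower, at 123 against 138 CPM (-0.21, adjusted p = 0.0476). The markers Cd8b1, Tcrg-C2, Cd79b, Ighm, Lyz2, Cd68, Epcam, Cdh1 and Pecam1 did not pass, with adjusted p from 0.0615 for Cdh1 to 0.893 for Cd8b1. The other markers of these cell types had too few UMIs for the test or were not analysed here, and no erythroid marker was analysed here. Among T cell markers, Cd4 rose by 0.63 (adjusted p = 8.8e-07), the receptor constant genes Trbc1 (-0.43, adjusted p = 0.0172) and Trbc2 (-0.38, adjusted p = 0.00926) were lower, and Cd3d, Cd3e, Cd3g and Trac did not pass.

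Within the clusters, genes with the largest changes are again those called with a mean log2 CPM of at least 4 and no overlap between genotypes. Plac8 was higher and the chemokine receptor gene Cxcr4 lower in KO-labelled mice in all 7. Plac8 rose by 0.70 ± 0.15 in unnamed 1 to 1.94 ± 0.18 in Th17 cells, where it stood at 398 ± 122 against 103 ± 30.8 CPM. Cxcr4 fell by 0.62 ± 0.17 in recirculating to 1.79 ± 0.37 in regulatory cells. Cd4 rose in 6 of 7 clusters, by 0.47 ± 0.06 in recirculating to 0.76 ± 0.08 in cycling cells. Cd7, Cd160, Fas and Trat1 each fell in 6. Of 919 genes called in any cluster, 529 were called in 1 and 234 in 3 or more.

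Recirculating cells had 416 of 7596 genes called, 165 up and 251 down. Besides Plac8, Crip2 (1.20 ± 0.19) and Vav3 (1.20 ± 0.23) rose most by this rule, and Smoc2 (-3.47 ± 0.40), Esm1 (-2.63 ± 0.26) and the cytokine gene Il22 (-2.19 ± 0.40) fell most. In unnamed 1, 276 of 5933 were called, 104 up and 172 down, with rises in Il2 (2.78 ± 0.43), Rasgrp4 (2.63 ± 0.43) and Itsn1 (2.41 ± 0.32) and falls in Cd7 (-2.25 ± 0.26), Gstm5 (-1.31 ± 0.19) and Trat1 (-1.29 ± 0.13). In cytotoxic cells, 191 of 6601 were called, 87 up and 104 down. Tmem154 (1.70 ± 0.23), Asb2 (1.64 ± 0.19) and Dkkl1 (1.48 ± 0.25) rose and Tff1 (-3.37 ± 0.48), Adam9 (-1.79 ± 0.30) and Asap2 (-1.71 ± 0.34) fell. Ccl5 was at 8083 ± 1650 against 16080 ± 1167 CPM in these cells (log2 fold change -0.98 ± 0.09, adjusted p = 1.8e-07). It was called lower in 4 of 7 clusters and stood at -0.01 ± 0.19 (adjusted p = 0.998) in recirculating cells. The limma test given below called no gene, Ccl5 included, as differing in effect between cytotoxic and recirculating cells. That does not show equal effects for Ccl5, since its estimates lie apart and the power of the test was not checked.

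In unnamed 3, 357 of 4242 genes were called, 131 up and 226 down, with rises in Plac8, Rcbtb2 (1.61 ± 0.21) and Vav3 (1.55 ± 0.23). Irs2 (-2.94 ± 0.38), the decoy receptor gene Il1r2 (-2.75 ± 0.31) and the growth factor gene Areg (-1.96 ± 0.25) fell most. Th17 cells had 283 of 5558 called, 140 up and 143 down. Jaml (1.56 ± 0.33) and Lgals3 (1.50 ± 0.17) rose, and Cxcl3 (-3.17 ± 0.33), Penk (-2.28 ± 0.46) and St6galnac1 (-2.09 ± 0.34) fell. In these Th17 cells Gzmb rose by 1.48 ± 0.17 (adjusted p = 1.1e-05) and Ifng by 0.94 ± 0.20 (adjusted p = 0.00579). Cycling cells had 288 of 5376 called, 131 up and 157 down, with rises in Crip2 (1.80 ± 0.25), Tnfsf11 (1.61 ± 0.18) and Bcl6 (1.46 ± 0.21) and falls in Esm1 (-2.46 ± 0.32), Cd7 (-2.18 ± 0.18) and Trat1 (-1.62 ± 0.15). Regulatory cells, from 5 KO-labelled and 3 WT-labelled mice, had 9 of 1754 called, 3 up and 6 down, among them Plac8, Camk2n1 (1.15 ± 0.23), Klrg1 (0.95 ± 0.21), Tmem176b (-3.02 ± 0.49), Cxcr4 and Il7r (-0.96 ± 0.19). The count was 0 without KO-labelled mouse 1 and 1 without KO-labelled mouse 2 or WT-labelled mouse 6, and with equal cells it was 1.

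A difference in effect between recirculating and cytotoxic cells was found for 0 of 6549 genes with limma, with 539 at an unadjusted p under 0.05. The lack of calls does not show that effects were equal, because the power of this test was not checked. The log2 fold changes in these clusters correlated across genes with r = 0.435, and genes are not independent replicates. Counts of calls in different clusters also differ with the number of cells, and the other pairs of clusters were not tested.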

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

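The test of Bcl6 without single mice was chosen only after its result was seen, as was the limit set on the 95% bound around the Bcl6 locus. In this part the other tests were written down before their results were seen. In 106 groups of mice tested for a single value far from the rest, 4 had one, and chance gives about 5.3. The groups covered cluster shares, depth, clonotype measures, ribosomal shares and CPM of the genes named over all cells, not shares of cells with a UMI. KO-labelled mouse 6 had the most UMIs in its genotype, 5523025 against 4686406 in the next mouse. WT-labelled mouse 6 had the fewest cells in clones of at least 2 cells, 70.1% against 77.9% in the next. Il17a stood at 45.0 CPM in WT-labelled mouse 5 against 207 CPM in the next lowest, and passed without that mouse (adjusted p = 0.00802). Tff1 stood at 36.6 CPM in KO-labelled mouse 6 against 11.995 CPM in the next highest. A T cell receptor clonotype was given for 16175 cells, which the comparisons by genotype above do not use.

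The numbers of changed genes were set against other divisions of the mice into groups of the same sizes. For all CD4 cells, 1 of 100 drawn splits, the real one, gave as many as 1405 genes, and the highest other gave 182. The real split was also the 1 of 100 with as many in recirculating cells (416, highest other 36), unnamed 1 (276, highest other 186), cytotoxic cells (191, highest other 8), unnamed 3 (357, highest other 83), Th17 cells (283, highest other 21) and cycling cells (288, highest other 21). In regulatory cells it was 1 of all 56 splits (9, highest other 6). By this count chance is an unlikely account of these results, though only 100 of 462 possible splits were drawn outside regulatory cells. The 9 genes of regulatory cells rest on single mice, since 0 were called without KO-labelled mouse 1 and 1 without KO-labelled mouse 2 or WT-labelled mouse 6. Chance cannot be excluded for the gene lists, since 16 of 100 splits gave 6 or more lists, up to 8.

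Bcl6 UMIs were higher in the mice given BCL-6-deficient cells. A shift in cluster make-up would have removed the difference with clusters weighted alike, but the log2 fold change was then 0.59 against 0.48. It did not rest on 1 mouse, since the lowest value without any 1 mouse was 0.44. Bcl6 rose in 4 of the 6 clusters tested, with -0.30 ± 0.18 in cytotoxic cells and -0.04 ± 0.18 in unnamed 3 not passing. Transcripts that keep their 5′ end but encode no working protein, loss of self-repression by BCL-6 and exchanged genotype labels stay open, because no value here tells them apart.

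Genes were called in 3 or more clusters for 234 genes, 229 of them in 1 direction. Donor strains can differ around a targeted gene, which might put such genes near Bcl6. With Bcl6 itself left out, 1 of the 68 genes within 10 Mb of it that were tested in 3 or more clusters, Lpp, was called in 3 or more clusters, against 229 of 5940 elsewhere, a ratio of 0.381 (one-sided Fisher exact p = 0.931). The ratio lay under the 1.5 written down as speaking against this explanation, and the 95% bound of 2.06 lay under the 3 that it needed. Lpp, which rose in 3 clusters, lies at 24393507 to 24992578, close to Bcl6 at 23965052 to 23988852. An effect limited to such a close neighbour cannot be judged from a window of 10 Mb. A strain difference farther from the gene stays open, and Itsn1 and Trat1 lie on the same chromosome outside that window.

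Cd8a was found in 484 of 9152 cells of WT-labelled mice and 59 of 9708 of KO-labelled mice, and within cytotoxic cells in 13.2% against 4.28%. Its share in Th17 cells of WT-labelled mice was 0.241%, although these were deeper, at a median of 3468 UMIs against 2424 in cytotoxic cells without Cd8a. CD8 T cells in the sort would carry Cd8b1, yet Cd8b1 UMIs came to 0.0861% of the 1162 Cd8a UMIs in those cells, and Cd4 was found in 57.0% of cytotoxic cells with Cd8a and 53.6% of those without. All cells of WT-labelled mice held 84 Cd8b1 UMIs, so the gene is captured, but how fully is open. A hypothesis is that CD4 T cells with a CD8 alpha homodimer may be fewer in KO-labelled mice, which surface staining of CD4 T cells for CD8 alpha and beta in both genotypes would test.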

How the results depend on the processing

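The relabellings, the fits without KO-labelled mice 1 and 2 and the lists with clusters weighted alike were chosen after seeing the data. The count of changed genes over all cells lay between 952 and 1507 under the alternatives that use all mice, between 1073 and 1867 (without KO-labelled mouse 6) with 1 mouse left out, and at 770 without KO-labelled mice 1 and 2. With equal cells per mouse, fewer UMIs entered and the counts were 227 in recirculating, 129 in unnamed 1, 73 in cytotoxic, 183 in unnamed 3, 122 in Th17 and 1 in regulatory cells. Without a filter on low counts they were 307 in cytotoxic and 44 in regulatory cells. Without KO-labelled mice 1 and 2 they were 175 in unnamed 1, 203 in unnamed 3, 176 in cycling and 0 in regulatory cells, with fewer mice. With 1 mouse left out, regulatory cells gave 0 (without KO-labelled mouse 1) to 12 genes.

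The cytotoxic and unnamed 1 differences in share kept their direction and passed in every alternative run. By nearest cells and by the classifier, the differences in percentage points were -5.55 and -8.25 for Th17, -0.0549 and 9.71 for unnamed 3, and 16.8 and 0.196 for recirculating cells. The nearest-cell labels returned few unnamed cells even in WT-labelled mice, and the classifier was preferred only after the first shares were seen, so neither decides between them. Recirculating cells were 2.03 points higher without KO-labelled mice 1 and 2. The cycling difference was -0.220 by nearest cells and -0.356 to 0.724 with 1 mouse left out. The cause of these changes was not tested.

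Over all cells, 0 lists passed with an estimated correlation. With clusters weighted alike 7 passed, and the Treg list turned from higher, without passing (median log2 fold change 0.39, adjusted p = 0.397), to lower and passing (-0.17, adjusted p = 0.00747). The share of cells with a Cxcr5 UMI was the single one of 10 genes to pass, 0 passed unthinned, and 0 to 1 passed with 1 mouse left out (0 without KO-labelled mouse 1, 2, 3, 5 or 6). Of 23 named genes called over all cells, 19 kept their call in every alternative. In regulatory cells, tested in 5 KO-labelled and 3 WT-labelled mice, 24% of simulated 1.5-fold changes were recovered.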

Other observations

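The tests of ribosomal protein genes were chosen only after their result was seen, and the clonotype measures were set after the data had been opened. The test of shared recirculating clones was written down before its result was seen. Ribosomal protein genes were lower in KO-labelled mice, over all cells and within the larger clusters. They took 21.2% ± 0.696 of the UMIs of KO-labelled and 23.6% ± 0.696 of those of WT-labelled mice (SD, n = 6 each, exact permutation p = 0.00216, adjusted p = 0.00346 over 8 comparisons). The share was 21.9986% ± 0.863 against 25.04% ± 0.680 in recirculating, 20.3% ± 0.738 against 23.6% ± 1.02 in Th17, and 16.8% ± 0.445 against 19.4% ± 0.540 in cycling cells, each with the same exact p. In cytotoxic cells it was 22.2% ± 0.635 against 23.4% ± 0.562 (exact p = 0.00649, adjusted p = 0.00742). The share was 20.9% ± 0.717 against 23.2% ± 1.04 in unnamed 1 (exact p = 0.00649, adjusted p = 0.00742). In unnamed 3 it was 23.6% ± 0.867 against 26.3% ± 0.927 (exact p = 0.00216, adjusted p = 0.00346). In regulatory cells it was 15.7% ± 1.03 against 17.6% ± 0.523 and did not pass (exact p = 0.0714, n = 5 and 3). Of 81 ribosomal protein genes tested over all cells, 64 fell and 0 rose, with a median log2 fold change of -0.18, which was -0.16 to -0.20 under the alternatives. Among genes that fell in 3 or more clusters and rose in 0, 59 of 145 were ribosomal protein genes. Over all cells, 647 of the 9780 other genes tested fell. Ribosomal protein genes hold a large part of the UMIs, so small shifts in them are called more readily. The mitochondrial genes mt-Co1, mt-Co2 and mt-Co3 fell in 6 clusters each, by a median of 0.22 to 0.26 on the log2 scale. Many ribosomal protein genes have pseudogene copies that share reads, so single values are uncertain and the share of all of them is given.

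Clonotypes were nearly always private to 1 mouse, 6347 of 6367, with 20 found in 2 mice. Of 5381 cells in clones of at least 10 cells, 7 lay outside the clone's main mouse, or 0.130%. At 1246 cells per mouse, KO-labelled mice held 563 ± 81.8 clonotypes against 449 ± 74.0 (SD, n = 6 each, exact permutation p = 0.0411, adjusted p = 0.0823 over 6 measures). Cells in clones of at least 2 cells made up 69.7% ± 4.89 against 78.0% ± 4.22 (exact p = 0.0195, adjusted p = 0.0584). Neither passes the adjustment. A clonotype was given for 83.7% ± 3.51 of cells against 88.2% ± 1.65 (exact p = 0.0195, adjusted p = 0.0584), with the same p as the clone measure.

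A hypothesis was that recirculating clones in KO-labelled mice would be shared less often with the other clusters. It was not borne out, since 64.0% ± 4.15 of recirculating cells against 61.7% ± 4.79 shared a clone (SD, n = 6 each, exact p = 0.377). With 88 recirculating and 820 other cells drawn per mouse, the shares were 59.2% ± 5.83 and 59.0% ± 4.78 (exact p = 0.942). The p at equal numbers meets what had been written down as speaking for cluster sizes. With no difference at the real numbers there was nothing for them to account for, a point raised after the values were known, so their part cannot be judged.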
